A study of Homo sapiens with 16 samples.

How the data were processed

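RNA of SK-MEL-2 cells was profiled in 16 libraries, 4 replicates in each of 4 groups, grouped by the treatment and replicate number in the titles. Per the labels' protocols, total RNA went into Illumina TruSeq stranded mRNA libraries that were pooled and sequenced as paired reads on a NovaSeq. RSEM 1.3.0, STAR 2.5.3a and the build GRCh38 (hg38) are named in the submitters' processing notes, and the annotation release and the strand setting are not given in the sources used here. Each deposited table holds, per gene, RSEM expected counts, TPM and FPKM with the gene's length and effective length, per the file headers. The deposited expected counts are not normalized, the deposited TPM are scaled by the authors to gene length and library, and the deposited FPKM were not used here. Of the expected counts above 0, 88.5% were whole numbers exactly as printed, and all were rounded before testing.

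The tables list 60603 gene IDs, of which 60306 matched a symbol in a table of gene names and 58528 matched GENCODE 29 when the ID version was left off. Gene types and coordinates are those of GENCODE 29 on GRCh38. Total expected counts ran from 20275158 to 35992287 per library, and the common biological coefficient of variation was 0.116. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom of 1.66 to 93.6, so each library counted as 1 replicate.

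Genes were kept with filterByExpr, which left 16186, and scaled with TMM factors. Each comparison was a contrast in 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3, glmQLFit and glmQLFTest with robust estimation) of all 16 libraries with 1 mean per group and no covariate, so that the groups shared 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05, and genes with an absolute log2 fold change of at least 1 were counted as well. Standard errors are the log2 fold change over the root of the F statistic. The departure from additivity was the contrast combination - BI6727 - MK-0752 + DMSO. CPM values use the TMM factors.

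A set of 36 gene lists was fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Lists with 5 or more tested members (35) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists; p-values quoted for a list are camera's unless stated. Camera with an estimated correlation and fry were the alternatives. An adjusted p with an estimated correlation is that of the whole list, also where it follows a named member. Each list given such a value had passed with the preset correlation over all tested genes. Counts of members are over all genes tested, with counts adjusted over the list alone beside them.

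Genes were named by rule. For each comparison with DMSO these were up to 8 genes with the largest rises and 8 with the largest falls among those called with a mean CPM of 5 or more, an unambiguous symbol and no overlap between treated and DMSO libraries; up to 4 called members of each called list with the smallest p; and always PLK1, NOTCH1, NOTCH2, NOTCH3, HES1, HEY1, NRARP, CDKN1A, MYC and MITF. The text leaves some of these out, smallest changes and largest p first, to stay near 30 per comparison. Some other genes named by the rule are not reported here, and no gene took their place. The other comparisons used the 6 largest changes in each direction and the same fixed genes, without the condition on libraries for the departure. List members named in those comparisons (MCM4, BIRC3, CAPN3, CYP51A1, SCD, XBP1, VEGFA, RRAGD, PDGFRB, BUB1, TYR and ASNS) were chosen after their values were seen, as the member with the smallest p of a list that held with an estimated correlation.

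The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) of the deposited TPM, no filter on low counts, a mean CPM of 5 or more, the replicate number as a block, only the groups compared, and each library left out in turn. A correction for transcript GC content (16027 tested genes had a value) and the removal of MK-0752 replicate 1 from comparisons without that group were added after the data were seen. Correlations of responses were set against 20 simulated draws of unchanged groups. For the departure, the residuals of a fit with additive effects of the agents on log2 CPM were shuffled between libraries and tested with limma-trend and camera, a test also added after the data were seen. So was a call of the departure in 2 libraries per group set against the agents' changes in the other 2.

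The steps were tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. For BI6727 against DMSO 91% of the 2-fold and 70% of the 1.5-fold changes were recovered among 15975 genes with 11 false calls. For the departure from additivity 76% and 45% were recovered among 15981 genes with 7 false calls.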

Results

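SK-MEL-2, a human melanoma cell line, was cultured for 48 h with vehicle (DMSO), with BI6727 at 20 nM, with MK-0752 at 100 µM, or with both agents at these doses. BI6727 (volasertib) inhibits PLK1, a kinase that acts in mitosis, and MK-0752 inhibits gamma-secretase, the protease that releases the active fragment of NOTCH receptors. Polyadenylated RNA was sequenced from 4 replicates per group, 16 libraries in all, and the expected counts summed to between 20275158 and 35992287 per library. The title of the series speaks of synergistic modulation, so each agent was compared with DMSO, the combination with DMSO and with each agent, and the combination with the sum of the changes of the agents. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

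HES1, a transcriptional repressor induced by NOTCH (ENSG00000114315.4, GRCh38 chromosome 3, 194136145 to 194138732, protein-coding in GENCODE 29), had 104.8 ± 8.75 CPM (SD, n = 4) in DMSO, 128.6 ± 11.4 with BI6727, 10.45 ± 0.457 with MK-0752 and 8.774 ± 1.36 with the combination. PLK1 itself (ENSG00000166851.15, chromosome 16, 23677656 to 23690367) had 92.52 ± 3.22 CPM in DMSO, 183.3 ± 4.98 with BI6727, 120.3 ± 15.9 with MK-0752 and 143 ± 12.1 with the combination. In a principal component analysis, component 1 held 39.1% of the variance and placed DMSO at -45.7 to -39, the combination at 34.5 to 49.1, and the agents given alone between them. MK-0752 replicate 1 lay apart on component 2, at -66.2. Its fragment length, read from the deposited effective lengths, was 237.4 nt against 281.7 to 284.9 nt in the other 3 MK-0752 libraries, and mitochondrially encoded genes took 1.32% of its counts against 3.79 to 4.17%.

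**Figure D1:**
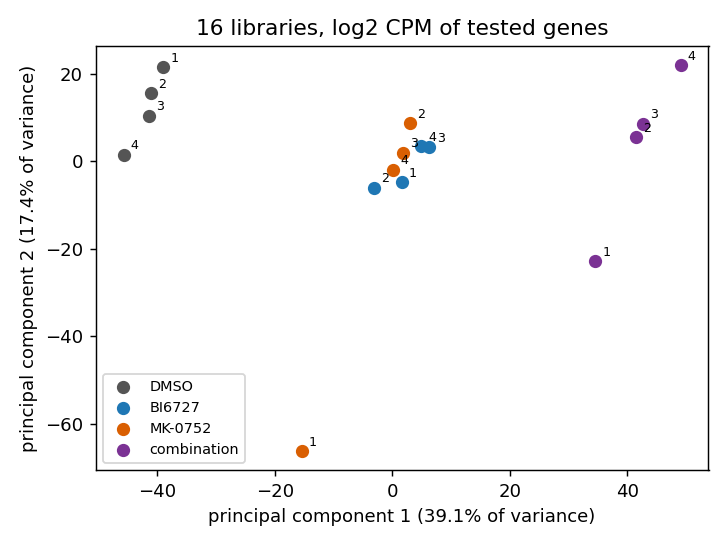
Principal components 1 and 2 of log2 CPM over the 16186 tested genes, with 1 point per library, coloured by group and numbered by replicate. The DMSO libraries lie at the left, the combination libraries at the right, and MK-0752 replicate 1 lies at -66.2 on component 2.

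**Figure D2:**
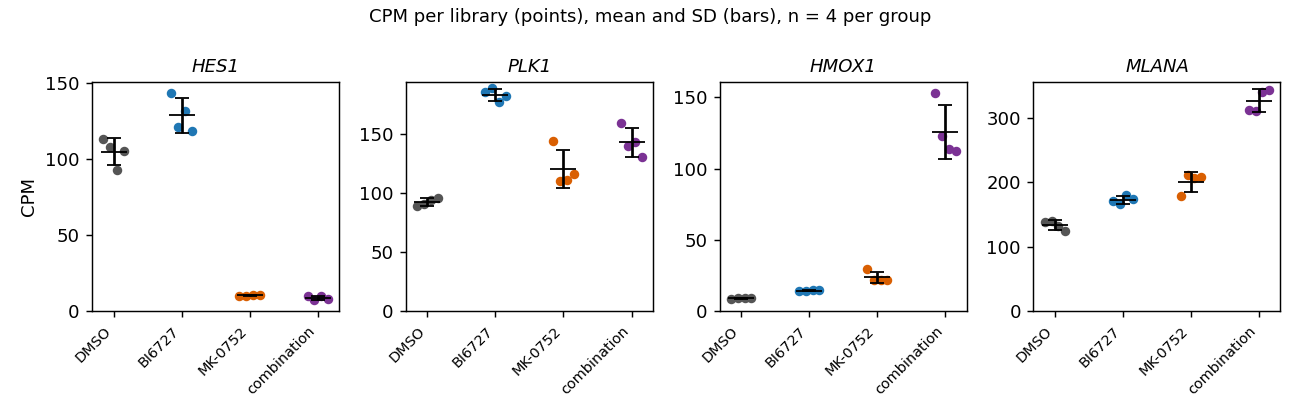
CPM of HES1, PLK1, HMOX1 and MLANA on linear axes from 0, with 1 point per library and bars for the mean and SD of 4 libraries. HES1 stood at 10.45 CPM with MK-0752 and 8.774 CPM with the combination, and HMOX1 at 125.5 CPM with the combination.

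BI6727 against DMSO shows what this compound at 20 nM changed, whether through PLK1 or not. Transcripts of G2 and M phase rose together: 29 of 30 tested members of the G2/M and mitotic spindle list were called higher and none lower, with a median log2 fold change of 0.55 (camera adjusted p = 3.1e-21). HMMR, a spindle protein, rose 2.38-fold, from 102.2 ± 3.29 to 243.5 ± 12 CPM (SD, n = 4). CCNB1, the mitotic cyclin B1, rose 1.67-fold, and PLK1 rose 1.98-fold. Of 30 G1/S and DNA replication genes 20 rose and none fell, among them CDC6, which loads the replicative helicase, at 1.73-fold, and MCM6, a subunit of that helicase, at 1.38-fold. When adjusted over the list alone, 29 G2/M and 21 G1/S genes were higher.

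Homologous recombination and Fanconi anaemia genes rose in 14 of 18 tested members, among them EXO1 by 1.54-fold and BRCA2 by 1.73-fold (adjusted p = 0.054 with an estimated correlation). Of 14 heat shock genes 8 rose, among them the chaperones DNAJA1 and HSPH1, both by 1.46-fold. Of 24 cholesterol biosynthesis genes 11 rose and none fell. Unfolded protein response chaperones had 11 members higher and 3 lower of 20, with HSPA5 up 1.39-fold and DNAJB11 up 1.32-fold (adjusted p = 0.055 with an estimated correlation). NRF2 antioxidant genes had 7 higher and 1 lower of 16, with SRXN1 up 1.48-fold and FTH1, ferritin heavy chain, up 1.31-fold (adjusted p = 0.055 with an estimated correlation, and 0.066 with the preset correlation among genes of a mean CPM of 5 or more). Fibroblast markers fell in 5 of 10 tested members (adjusted p = 0.055 with an estimated correlation), among them COL1A2 by 2.82-fold and S100A4 by 2.81-fold. The higher members numbered, adjusted over the list alone, 15, 10, 11, 14 and 8 in the 5 lists that rose, with 1 cholesterol, 3 chaperone and 1 NRF2 gene lower, and 5 fibroblast markers were lower.

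The largest rises with BI6727 under the fixed rule were in DHRS2 (3.68-fold), TXNIP, an arrestin-like regulator of glucose uptake (2.89-fold), MEIOSIN (2.86-fold), FLG (2.44-fold) and FGFR3 (2.42-fold). The largest falls were in ITGA10 (4.56-fold), LINC01139 (4-fold), F13A1 (3.93-fold), SNHG20 (3.38-fold) and VCAN, the matrix proteoglycan versican (3.22-fold, from 56.83 ± 2.5 to 17.67 ± 1.3 CPM). CDKN1A, the cell cycle inhibitor p21, rose 1.35-fold and NOTCH2 1.12-fold, while HEY1 fell 1.16-fold. On log2(TPM + 1), FLG had a log2 change of 0.73 instead of 1.29 and BRCA2 0.43 instead of 0.79. NOTCH3, at 1.542 CPM in DMSO, fell 2.4-fold, a call that ended with limma on log2(TPM + 1) (adjusted p = 0.159). HES1 had a log2 fold change of 0.30 ± 0.09 (SE, adjusted p = 0.014), and its call ended without DMSO replicate 3 (0.24, adjusted p = 0.0711) or BI6727 replicate 1 (0.23, adjusted p = 0.0754). NRARP, at 0.3518 CPM in DMSO and 0.6814 with BI6727, had an adjusted p of 0.021, and of 0.0524, 0.0612 and 0.0737 without DMSO replicate 2, DMSO replicate 4 and BI6727 replicate 4, and 0.0542 with DESeq2. Its log2 fold change of 0.93 was 0.20 on log2(TPM + 1). MYC did not pass (adjusted p = 0.727). NOTCH1 did not pass (adjusted p = 0.229) but did after a GC correction (0.00179) and with only these groups fitted (0.0203). MITF, with a log2 fold change of -0.25 ± 0.1, did not pass (adjusted p = 0.0612). It did without MK-0752 replicate 1 (7.17e-06), which enters through the shared spread, the gene filter and the scaling. It also passed with upper-quartile factors (0.0411), limma on log2(TPM + 1) (0.0315), a mean CPM of 5 or more (0.0339), the replicate block (0.0465), a GC correction (8.97e-05) and only these groups fitted (9.3e-07).

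In all, 2725 genes were higher and 3104 lower with BI6727 among 16186 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 87 rose and 656 fell by 2-fold or more. With only these groups fitted 4602 were higher, 8806 in all, and after a GC correction 4721 were lower. Higher genes made up 46.7% of the calls, from 37.1% with upper-quartile factors to 52.3% with only these groups fitted. Of 35 lists 7 were called higher and 1 lower, 4 of them also with an estimated correlation. Chance was not excluded for this number of lists, since another split of the 8 libraries called 10. That split kept most libraries of each group together, and so part of the treatment difference, and cannot decide on chance.

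MK-0752 against DMSO shows what the compound at 100 µM changed, through gamma-secretase or otherwise. HES1 fell 10-fold (log2 fold change -3.32 ± 0.1 (SE), adjusted p = 8.65e-12), with the MK-0752 libraries below the DMSO libraries in all 4 replicates. HEY1, another NOTCH target, fell 1.58-fold, from 28.68 ± 2.46 to 18.16 ± 0.581 CPM (SD, n = 4). The list of NOTCH targets as a whole did not pass, with 4 members lower and 2 higher of 12, also adjusted over the list alone (median -0.20, adjusted p = 0.21). NRARP and MYC, also on that list, had log2 fold changes of -0.35 ± 0.35 and 0.06 ± 0.06. NOTCH receptors, ligands and gamma-secretase parts had 6 higher and 4 lower of 21 (adjusted p = 0.82), with a median of -0.03 and a mean of -0.04 although the test leaned upwards.

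Lipid and stress genes rose. Of 24 cholesterol biosynthesis genes 17 were higher and none lower (median 0.55, adjusted p = 9.7e-10), among them CYP51A1, lanosterol demethylase, by 1.96-fold. Fatty acid synthesis genes rose in 8 of 15 members, with ACLY up 1.28-fold. NRF2 antioxidant genes rose in 14 of 16, among them HMOX1, haem oxygenase 1, by 2.59-fold. ATF4 targets rose in 15 of 22, with asparagine synthetase ASNS up 1.4-fold, and unfolded protein response chaperones in 16 of 20 with 1 lower, with HSPA5 up 1.72-fold. Lysosome and autophagy genes rose in 11 of 24 with 1 lower. In these 6 lists, adjusted over the list alone, 22, 8, 15, 18, 16 and 11 members were higher. Heat shock genes rose in 8 of 14 with 1 lower, and in 10 adjusted over the list alone (DNAJA1 1.31-fold, adjusted p = 0.069 with an estimated correlation). Xenobiotic metabolism genes rose in 4 of 6 with 1 lower by both adjustments (ALDH1A3 1.7-fold, adjusted p = 0.15 with an estimated correlation).

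Genes of the dedifferentiated and invasive state fell in 11 of 17 members with 1 higher, and in 13 with 2 higher adjusted over the list alone (median -0.32, adjusted p = 0.0029), among them THBS1, a matrix glycoprotein, by 1.39-fold. Fibroblast markers fell in 6 of 10, with PDGFRB down 2.05-fold. Collagen and matrix genes had 7 lower and 2 higher of 18, with fibronectin FN1 down 2.49-fold, from 3077 ± 78.2 to 1234 ± 72.2 CPM (adjusted p = 0.16 with an estimated correlation; 0.063 with the preset correlation without MK-0752 replicate 3). Cytosolic ribosomal protein genes fell in 11 of 28 (adjusted p = 0.32 with an estimated correlation; 0.055 and 0.069 with the preset correlation without MK-0752 replicates 2 and 3). These 3 counts were the same adjusted over the list alone.

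G2/M genes had 10 higher and 1 lower of 30, with HMMR up 1.44-fold, and 11 and 1 adjusted over the list alone. The list had a camera adjusted p of 0.0085, and of 0.4 with an estimated correlation. G1/S genes had 8 higher and 1 lower of 30, with CDC6 up 1.34-fold, and 9 and 1 adjusted over the list alone. For this list the camera adjusted p was 0.0087, and 0.15 with an estimated correlation. Without MK-0752 replicate 1 the G2/M list had 14 higher and 2 lower and the G1/S list 14 higher and 3 lower. The p53 list had 10 higher and 3 lower of 24 by both adjustments, with CDKN1A up 1.55-fold (adjusted p = 0.069 with an estimated correlation; 0.052 with the preset correlation without MK-0752 replicate 1). Among genes of a mean CPM of 5 or more the G2/M, G1/S, p53 and matrix lists had adjusted p values of 0.062, 0.057, 0.057 and 0.053, and after a GC correction the G1/S and p53 lists had 0.086.

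Other large rises were in ANGPTL4 (3.17-fold), OSGIN1 (2.53-fold), DUSP2 (2.42-fold) and BIRC3, an inhibitor of apoptosis (2.35-fold). MK-0752 replicate 1 held 106 CPM of ANGPTL4 and 72.4 CPM of OSGIN1, against 40.7 to 46.9 and 24.2 to 32.2 in the other 3 libraries, and without it the log2 fold change of OSGIN1 was 0.85 instead of 1.34. After HES1 the largest falls were in LINC01139 (3.47-fold), the immediate early genes FOSB (3.33-fold) and NR4A2 (3.19-fold), and CLDN11, a tight junction protein (3.13-fold). PLK1 rose 1.3-fold. NOTCH1 and MITF did not pass (adjusted p = 0.332 and 0.258), and MITF passed after a GC correction (0.00674). NOTCH2 passed (log2 fold change 0.12, adjusted p = 0.0331), but not without DMSO replicate 2, 3 or 4 (0.0591, 0.0684 and 0.0834) or MK-0752 replicate 2 or 3 (0.0631 and 0.054). Nor did it pass with upper-quartile factors (0.169), no filter on low counts (0.19), a mean CPM of 5 or more (0.105), the replicate block (0.0635), a GC correction (0.0731) or only these groups fitted (0.0691). NOTCH3 passed (-0.86, adjusted p = 0.0217), but not without DMSO replicate 3 or 4 (0.062 and 0.058) or MK-0752 replicate 3 or 4 (0.0639 and 0.0687), nor with limma on log2(TPM + 1) (0.64) or only these groups fitted (0.0772).

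With MK-0752, 2377 genes were called higher and 2509 lower, of which 85 and 530 changed by 2-fold or more. Without MK-0752 replicate 1 the calls were 3664 higher and 3262 lower, and after a GC correction 4061 were lower. With only these groups fitted 1635 were higher and 1858 lower. Higher genes made up 48.6% of the calls, from 38.6% with upper-quartile factors to 52.9% without MK-0752 replicate 1. Of 35 lists 11 were called higher and 4 lower, 8 of them also with an estimated correlation. Chance was not excluded for this number of lists, since another split of the 8 libraries called 17. That split also kept most libraries of each group together, and so part of the treatment difference, and cannot decide on chance. Without MK-0752 replicate 3, 2 lists were called lower.

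The combination was called different from DMSO in 8406 genes, 4127 higher and 4279 lower, and 266 and 1581 by 2-fold or more. With limma on log2(TPM + 1) 2384 were higher, and among genes of a mean CPM of 5 or more, which are fewer, 2819 were lower. Melanocytic genes rose and invasive genes fell. Of 21 pigmentation and MITF target genes 16 were higher and none lower (median 0.43, adjusted p = 3.4e-06; adjusted p = 0.088 with an estimated correlation), among them the melanosome protein MLANA (ENSG00000120215.9, chromosome 9, 5890802 to 5910606), which rose 2.44-fold from 134 ± 7.52 to 326.5 ± 17.3 CPM (SD, n = 4). Of 17 dedifferentiated and invasive genes 13 were lower and 1 higher (median -1.06, adjusted p = 2e-06). Fibroblast markers fell in 7 of 10 with 1 higher, with PDGFRB down 4.7-fold (log2 fold change -2.23, and -1.37 on log2(TPM + 1)). Collagen and matrix genes had 10 lower and 4 higher of 18, with VCAN down 6.28-fold (adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone, 18 pigmentation genes were higher and 13, 7 and 10 members of the other 3 lists lower.

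NRF2 antioxidant genes rose in 13 of 16, led by HMOX1 (ENSG00000100292.17, chromosome 22, 35380361 to 35394214), which went from 9.188 ± 0.337 to 125.5 ± 19.1 CPM, 13.6-fold. Cholesterol biosynthesis genes rose in 18 of 24 with 1 lower (CYP51A1 2.37-fold), fatty acid synthesis genes in 9 of 15 (GPAM 1.93-fold), unfolded protein response chaperones in 15 of 20 with 1 lower (DNAJC3 2.08-fold) and lysosome and autophagy genes in 15 of 24 with 3 lower (GLA 1.67-fold). Adjusted over the list alone, 13, 18, 9, 16 and 15 members were higher. These 5 lists and the invasive and fibroblast lists also passed with an estimated correlation.

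G2/M genes were higher in 25 of 30 with 1 lower, with HMMR up 2.05-fold and PLK1 up 1.55-fold (adjusted p = 0.11 with an estimated correlation). Homologous recombination genes rose in 11 of 18 with 2 lower (EXO1 1.48-fold, adjusted p = 0.23 with an estimated correlation, and 0.092 with the preset correlation among genes of a mean CPM of 5 or more). Heat shock genes rose in 10 of 14 with 1 lower (HSPH1 1.56-fold, adjusted p = 0.11 with an estimated correlation) and xenobiotic metabolism genes in 5 of 6 (NQO1 1.81-fold, adjusted p = 0.12 with an estimated correlation). Replication-dependent histone genes rose in 8 of 12 (H1-2 1.83-fold, adjusted p = 0.074 with an estimated correlation). Their copies are nearly identical, so that reads can be split between them and their levels are uncertain. Their transcripts are also mostly not polyadenylated, so libraries of polyadenylated RNA hold only part of them, and the rise may not be one of all their transcripts. These 5 lists had 25, 11, 12, 5 and 9 members higher adjusted over the list alone.

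Mitochondrially encoded genes rose in 12 of 13 by both adjustments (median 0.87, MT-ND6 2.28-fold, adjusted p = 0.46 with an estimated correlation), and their share of counts was 5.35 ± 0.494% against 3.282 ± 0.144% in DMSO. With MK-0752 alone 1 of the 13 was higher (adjusted p = 0.82), but without MK-0752 replicate 1, the library at 1.32%, 12 were higher (median 0.45, adjusted p = 3.6e-05). Ribosomal protein genes fell in 14 of 28, also adjusted over the list alone (RPL10A 1.25-fold, adjusted p = 0.22 with an estimated correlation). Immediate early genes had 11 lower and 3 higher of 20, also adjusted over the list alone, with NR4A2 down 4.03-fold (adjusted p = 0.18 with an estimated correlation; 0.071 with the preset correlation after a GC correction). Epithelial markers fell in 5 of 8, and in 6 with 1 higher adjusted over the list alone, with the keratin KRT8 down 3.77-fold (adjusted p = 0.12 with an estimated correlation). Their preset adjusted p was 0.071, 0.099, 0.083 and 0.091 without DMSO replicates 1 to 4 and 0.083 without combination replicate 3. The list of fatty acid oxidation and PPAR targets had 7 higher and 3 lower of 13, and 8 and 3 adjusted over the list alone (adjusted p = 0.12 with an estimated correlation, and 0.065 with the preset correlation among genes of a mean CPM of 5 or more). Its preset adjusted p of 0.045 was 0.051 to 0.071 with any 1 DMSO library left out, 0.065 to 0.091 with any 1 combination library left out 0.067 after a GC correction and 0.093 without MK-0752 replicate 1.

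Among single genes, OSGIN1 (3.79-fold), PIK3R3, a regulatory subunit of PI3-kinase (3.72-fold), NFATC2 (3.4-fold) and LINC02119 (3.28-fold) rose most after HMOX1. HES1 fell 11.9-fold, F13A1 9.31-fold, UCA1 7.6-fold, the water channel AQP1 7.49-fold and the integrin ITGB4 7.15-fold. On log2(TPM + 1) the log2 change of F13A1 was -2.06 instead of -3.22 and that of ITGB4 -1.38 instead of -2.84. MYC fell 1.4-fold, HEY1 1.4-fold and NRARP 2.72-fold from under 1 CPM (log2 fold change -1.44, and -0.17 on log2(TPM + 1)). NOTCH3 fell 3.62-fold, a call that ended with limma on log2(TPM + 1) (adjusted p = 0.198). CDKN1A rose 1.23-fold and NOTCH2 1.16-fold, with log2 fold changes of 0.29 and 0.21 that were 0.17 and 0.11 on log2(TPM + 1), and 0.13 for NOTCH2 with upper-quartile factors. NOTCH1 did not pass (adjusted p = 0.35) but did after a GC correction (0.00163). The call of MITF (log2 fold change 0.28 ± 0.1, adjusted p = 0.0253) ended without DMSO replicate 2 (0.0529), DMSO replicate 4 (0.0598), combination replicate 3 (0.0553) or combination replicate 4 (0.0631). It also ended with upper-quartile factors (0.126), limma on log2(TPM + 1) (0.34), no filter on low counts (0.055) and a mean CPM of 5 or more (0.0751), and after a GC correction the log2 fold change was 0.13. Higher genes made up 49.1% of all calls, from 32.8% with limma on log2(TPM + 1) to 51.1% among genes of a mean CPM of 5 or more. Of 35 lists 13 were called higher and 6 lower, 7 of them also with an estimated correlation. Chance was not excluded for this number of lists, since another split of the 8 libraries called 21. Here too the split kept most libraries of each group together, and so part of the treatment difference, and cannot decide on chance.

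**Figure D3:**
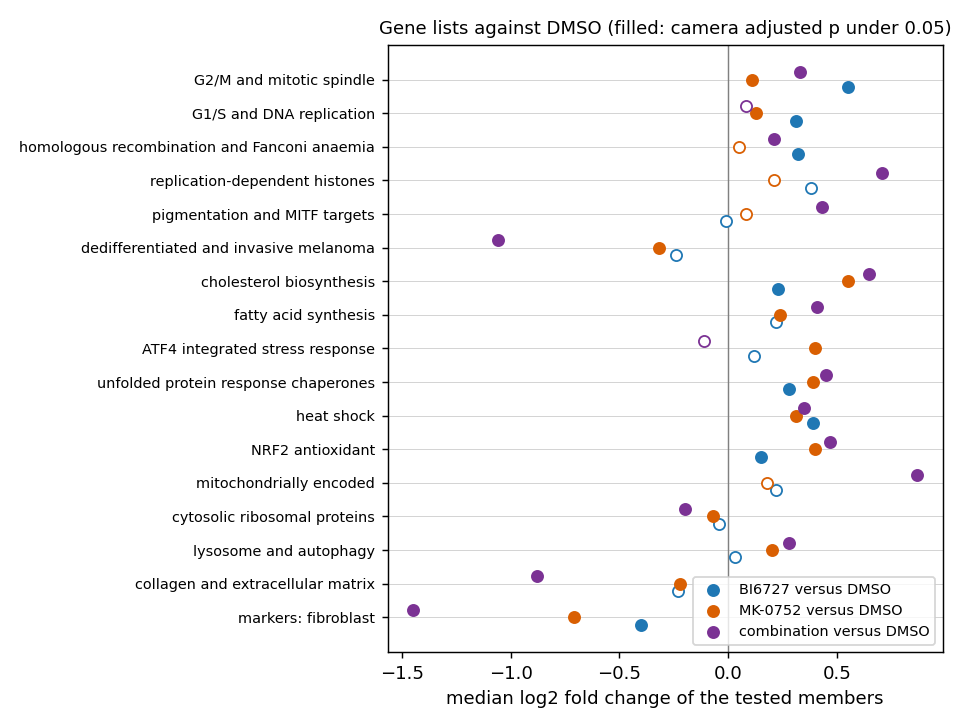
Median log2 fold change of the tested members of 17 fixed gene lists against DMSO, with 1 point per list and comparison, filled where the camera adjusted p was under 0.05. In the combination the invasive list stood at -1.06 and the pigmentation list at 0.43.

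The combination against BI6727 shows what MK-0752 added in cells given BI6727. HES1 fell 14.7-fold and HMOX1 rose 8.74-fold, from 14.37 to 125.5 ± 19.1 CPM (SD, n = 4). Pigmentation genes rose in 15 of 21 members with none lower (median 0.51, adjusted p = 5.2e-11), including SLC24A5, an ion exchanger of melanosomes, by 2.39-fold, and CAPN3 by 1.54-fold. Invasive genes fell in 13 of 17 with none higher (median -0.95). Cell cycle genes stood below their level with BI6727 alone: G1/S genes were lower in 17 of 30 with none higher (MCM4 1.31-fold), and G2/M genes in 19 of 30 with none higher (adjusted p = 0.057 with an estimated correlation), PLK1 by 1.28-fold. Adjusted over the list alone, 17 pigmentation genes were higher, and 13 invasive, 18 G1/S and 24 G2/M genes were lower.

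Cholesterol biosynthesis genes rose in 16 of 24 (CYP51A1 1.87-fold), NRF2 genes in 11 of 16, unfolded protein response chaperones in 11 of 20 (XBP1 1.41-fold) and fatty acid synthesis genes in 7 of 15 with 1 lower (SCD 1.58-fold). Lysosome and autophagy genes rose in 14 of 24 with 1 lower (RRAGD 1.7-fold) and apoptosis regulators in 9 of 19 with 1 lower (BIRC3 2.29-fold). Hypoxia and glycolysis genes had 11 lower and 4 higher of 21 (VEGFA 1.49-fold lower), and fibroblast markers 5 lower and 1 higher of 10 (PDGFRB 3.63-fold lower, a log2 fold change of -1.86 that was -1.18 on log2(TPM + 1)). Adjusted over the list alone, the rising lists had 16, 13, 12, 8, 15 and 9 members higher and the falling lists 12 and 5 lower. Each of these 8 lists also passed with an estimated correlation, and the apoptosis list did not pass with the preset correlation among genes of a mean CPM of 5 or more (adjusted p = 0.094). NOTCH targets had 6 lower and 2 higher of 12, also adjusted over the list alone (adjusted p = 0.057 with an estimated correlation; 0.14 with the preset correlation after a GC correction and 0.11 among genes of a mean CPM of 5 or more).

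Besides HES1, PLAC8 (5.22-fold), the keratin KRT7 (4.92-fold), the WNT antagonist DKK1 (4.33-fold), AQP1 (4.21-fold) and CAVIN2 (4.18-fold) fell most, and RAB11FIP4 (3.16-fold), NFATC2 (3.01-fold), XYLT1 (2.4-fold) and PKNOX2 (2.3-fold) were among the largest rises. MITF rose 1.44-fold, MYC fell 1.37-fold, HEY1 fell 1.2-fold (log2 fold change -0.27, and -0.45 on log2(TPM + 1)), and NOTCH1, NOTCH2 and NOTCH3 did not pass. NRARP, at 0.0456 to 0.256 CPM in the combination libraries, had a log2 fold change of -2.37, and of -0.37 on log2(TPM + 1). CDKN1A had a log2 fold change of -0.14 ± 0.05 (adjusted p = 0.0523). It passed without MK-0752 replicate 1 (0.0432), with upper-quartile factors (0.0187), with limma on log2(TPM + 1) (0.0108) and among genes of a mean CPM of 5 or more (0.0268). In all 2379 genes were higher and 2359 lower, and 82 and 538 by 2-fold or more. Higher genes made up 50.2% of the calls, from 29.5% with limma on log2(TPM + 1) to 55.8% with only these groups fitted. Without MK-0752 replicate 1, which is in neither group but enters the shared spread, the gene filter and the scaling, 3900 were higher and 3206 lower. With limma on log2(TPM + 1) 1140 were higher, and after a GC correction 3658 were lower. Of 35 lists 10 were called higher and 12 lower, 11 of them also with an estimated correlation.

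The combination against MK-0752 shows what BI6727 added in cells given MK-0752. HMOX1 rose 5.28-fold, from 23.83 to 125.5 ± 19.1 CPM (SD, n = 4), and TXNIP 2.78-fold, followed by its paralog ARRDC4 (2.42-fold), the lipid-binding myelin protein PMP2 (2.35-fold), TRIM48 (2.27-fold) and PIK3R3 (2.2-fold). Invasive genes fell in 11 of 17 with 1 higher (median -0.64, adjusted p = 2.7e-07). Cholesterol biosynthesis genes rose in 10 of 24 with 1 lower. Of the 17 lists called, 7 higher and 10 lower, these 2 also passed with an estimated correlation. Pigmentation genes rose in 17 of 21 with none lower (adjusted p = 0.054 with an estimated correlation), G2/M genes rose in 18 of 30 with none lower (adjusted p = 0.088 with an estimated correlation), and ATF4 targets fell in 15 of 22 with 1 higher (adjusted p = 0.054 with an estimated correlation). Counts adjusted over the list alone were 12 invasive genes and 15 ATF4 targets lower, and 13 cholesterol, 17 pigmentation and 19 G2/M genes higher.

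The largest falls were in FBLN2 (5.46-fold), PRDM8 (4.86-fold), ITGB4 (4.71-fold), KRT7 (4.68-fold), AKR1C1, whose near-identical paralogs make its level uncertain (4.62-fold), and KLF2 (4.29-fold). Of these, KRT7 and AKR1C1 stood apart in MK-0752 replicate 1, at 16.7 and 52 CPM. The other MK-0752 libraries held 7.1 to 8.6 and 47.2 to 47.5 CPM. On log2(TPM + 1) the log2 changes of FBLN2, PRDM8 and ITGB4 were -1.44, -1.23 and -0.98 instead of -2.45, -2.28 and -2.24. MYC fell 1.46-fold and MITF rose 1.35-fold, which did not pass with only these groups fitted (adjusted p = 0.0622). CDKN1A fell 1.26-fold, and its call ended after a GC correction (adjusted p = 0.126). HES1 had a log2 fold change of -0.25 ± 0.1 (adjusted p = 0.0805) and passed without combination replicate 3 (0.0393), with upper-quartile factors (0.047) and with limma on log2(TPM + 1) (0.0175), and NOTCH1 did not pass (0.9). NOTCH2 (0.0682) passed without MK-0752 replicate 1 or 3 or combination replicate 1 (0.0158, 0.0457 and 0.0108) and with DESeq2 (0.0236), and NRARP (0.0775) without combination replicate 2 (0.0243) and with limma-voom (0.0382). PLK1 (log2 fold change 0.25, adjusted p = 0.0231) did not pass without MK-0752 replicate 2 or 4 or combination replicate 1 (0.0603, 0.0553 and 0.0601) or with only these groups fitted (0.123). HEY1 (0.18, adjusted p = 0.0444) did not pass without MK-0752 replicate 2 or 3 or combination replicate 3 or 4 (0.074, 0.0766, 0.104 and 0.0644). It also failed with upper-quartile factors (0.113), limma-voom (0.0597), limma on log2(TPM + 1) (0.525), no filter on low counts (0.139), a mean CPM of 5 or more (0.0626), the replicate block (0.0632), a GC correction (0.0991) and only these groups fitted (0.101). NOTCH3 (-1, adjusted p = 0.0318) did not pass without MK-0752 replicate 1 or combination replicate 1, 2 or 3 (0.102, 0.0721, 0.0943 and 0.0593), nor with limma on log2(TPM + 1) (0.538), the replicate block (0.0537), a GC correction (0.091) or only these groups fitted (0.109).

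In all 2227 genes were higher and 2428 lower than with MK-0752 alone, 48 and 577 by 2-fold or more, and 918 and 1145 were called when only these 8 libraries were fitted. With limma on log2(TPM + 1) 765 were higher. Higher genes made up 47.8% of the calls, from 19.8% with limma on log2(TPM + 1) to 52.5% without MK-0752 replicate 1.

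The departure from additivity tests, gene by gene on the log2 scale, whether the combination differed from the sum of the changes of the agents. Cell cycle genes fell short of the sum: 22 of 30 G2/M genes (median -0.35, adjusted p = 2.5e-13) and 15 of 30 G1/S genes (adjusted p = 7.9e-11) lay below it and none above, with 23 G1/S genes below after a GC correction. Among them were BUB1, a spindle checkpoint kinase, at -0.63 ± 0.07 (SE, n = 4 per group), MCM4 at -0.48 ± 0.05 and PLK1 at -0.74 ± 0.11. Pigmentation genes exceeded it in 13 of 21 members with none below (median 0.42, adjusted p = 3.7e-09), with tyrosinase TYR at 0.87 ± 0.11 and MITF at 0.68 ± 0.14. Invasive genes lay below it in 9 of 17 (median -0.59). ATF4 targets lay below it in 14 of 22, with ASNS at -0.55 ± 0.07. Adjusted over the list alone, 25 G2/M, 18 G1/S, 11 invasive and 17 ATF4 genes lay below and 16 pigmentation genes above. These 5 lists also passed with an estimated correlation. Of 35 lists 2 were called higher and 10 lower, and another split of the 16 libraries, which also moves the agents' own effects, called 17. With the residuals of the additive fit shuffled 99 times, a test chosen after the data were seen, at most 10 lists were called. Without DMSO replicate 4, combination replicate 2 or combination replicate 4, 1 list was called higher.

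HMOX1 stood furthest above the sum, at 1.76 ± 0.15, followed by LINC01139 (1.49), ITGA10 (1.40), the mitochondrial ribosomal RNA MT-RNR1, whose nuclear copies make its level uncertain (1.37), LINC00622 (1.33) and the phosphodiesterase SMPDL3A (1.33). ITGA10 fell with each agent, from 13.28 CPM in DMSO to 2.907 with BI6727 and 5.811 with MK-0752, and stood at 3.356 with the combination. FLNC (-2.16), G0S2 (-2.14), KRT7 (-1.89), IGFN1 (-1.82), GRAMD2B (-1.82) and SLC27A2 (-1.67) lay furthest below. In MK-0752 replicate 1, FLNC, KRT7 and IGFN1 stood at 33.1, 16.7 and 91.6 CPM. The other MK-0752 libraries held 13.9 to 15.6, 7.1 to 8.6 and 48.6 to 52.7 CPM, so that replicate lowers these departures. It also held less LINC01139 and MT-RNR1, which raises their departures, and more HMOX1, which lowers its departure. The calls of these genes held without that replicate. CDKN1A (-0.76), HES1 (-0.55) and MYC (-0.51) also departed from the sum, and NOTCH1, NOTCH2 and NOTCH3 did not pass. HEY1 (0.39) passed, but not with limma on log2(TPM + 1) (adjusted p = 0.0597), and NRARP (-2.02, and -0.31 on log2(TPM + 1)) passed, but not after a GC correction (0.0656). In all 2508 genes departed, 1254 in each direction, and 201 above and 181 below by 2-fold or more. For 2061 of them the departure had the sign opposite to the sum of the changes, and for 447 the same sign. The departure and the sum share libraries with opposite signs, which favours the first of these. The departure was also called in 2 libraries per group, with the sum taken from the other 2. With the departure from replicates 3 and 4, 2 and 4, and 2 and 3, 81.9, 79.6 and 79.8% of the calls had the opposite sign. Noise independent between libraries favours neither sign there. A deviation common to all DMSO libraries, or to all libraries of an agent, would still favour the opposite sign, and this was not tested. With the departure from replicate 1 and replicate 2, 3 or 4, edgeR called 0 genes, and 1782, 2076 and 1763 had an unadjusted p under 0.05. Without MK-0752 replicate 1, 4158 genes departed, and 4486 after a GC correction. With limma on log2(TPM + 1) 719 lay above. Higher genes made up 50% of the calls, from 32.3% with limma on log2(TPM + 1) to 55.4% without DMSO replicate 4.

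Of the 4127 genes higher with the combination 1240 were also higher with each agent, and of the 4279 lower genes 1608 were also lower with each. Another 1358 higher and 1339 lower genes were called in that direction with neither agent, and 229 and 262 of these also departed from additivity in that direction. BI6727 and MK-0752 shared 1356 higher genes and 1701 lower genes, and 146 genes were called in opposite directions. Both comparisons use the same DMSO libraries. Across genes, which are not independent replicates, the log2 fold changes of the agents correlated at 0.69, and at 0.50 to 0.59 with the DMSO libraries split 2 and 2. Simulated unchanged groups against shared DMSO libraries gave 0.51 on average over 20 draws, with a highest value of 0.55. This is a reference for the 0.69 only. With the DMSO libraries split, the changes of the agents share no library, and that case was not simulated. A deviation common to all DMSO libraries would still raise the correlation there, and this was not tested. With shared DMSO libraries the covariance of the changes was 0.15 against a simulated 0.026, a difference of 0.13.

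The effect of MK-0752 in cells given BI6727 correlated across genes with its effect alone at 0.39, and that of BI6727 in cells given MK-0752 at 0.43. These pairs share no library. Of 4886 genes called with MK-0752 alone 2044 were called in the same direction in cells given BI6727 and 238 in the opposite direction. Of 5829 called with BI6727 alone 2333 were called in the same direction in cells given MK-0752 and 208 in the opposite direction.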

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

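The tests of GC content and of a wrong label for MK-0752 replicate 1, and of genomic DNA in the DMSO libraries, were chosen only after the result was seen, as was the GC correction itself. Each of 404 sets of 4 replicate values, of library measures and of genes named in the text, was searched for 1 library far from the other 3 (Dixon's test). This picked out 48, where chance gives about 20, and 26 of them were in MK-0752 replicate 1.

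In MK-0752 replicate 1, fragment length was 237.4 nt, mitochondrially encoded genes took 1.32% of counts and long noncoding RNAs 0.898%. It held more HSPA5 (1250 CPM), S100A4 (22.4), PLK1 (144), ANGPTL4 (106), HMOX1 (29.8), OSGIN1 (72.4), H1-2 (27.4), NQO1 (865), KRT8 (342), KRT7 (16.7), AKR1C1 (52), FLNC (33.1) and IGFN1 (91.6) than the other 3 MK-0752 libraries. It held less LINC01139 (3.31 CPM), MITF (117), CYP51A1 (103), MLANA (178), GLA (72), PLAC8 (3.97), SCD (168), ARRDC4 (5.9), TRIM48 (36.8) and MT-RNR1 (329). In the MK-0752 group CDKN1A stood apart in replicate 4, at 35.9 CPM.

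In the BI6727 group, replicate 1 had the highest total (35.99, in units of 1e+06 counts) and stood apart for NOTCH2 (1070 CPM), UCA1 (21.4) and SLC27A2 (7.19), replicate 2 for HMMR (225), DNAJB11 (104) and SMPDL3A (4.34), replicate 3 for FLG (23.9), SNHG20 (3.98) and its mitochondrial share (3.19%), and replicate 4 for XBP1 (28.5). In the DMSO group, replicate 1 stood apart for ITGA10 (12.1 CPM) and PMP2 (26.9), replicate 2 for FLG (7.02), replicate 3 for UCA1 (55.5) and replicate 4 for RAB11FIP4 (56.1). In the combination group, replicate 1 stood apart for BIRC3 (45.6 CPM), ACLY (598) and G0S2 (6.1), replicate 2 for XYLT1 (70.5) and replicate 3 for SNHG20 (3.42).

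The effect of each agent differed with and without the other in 2508 genes by the test of the difference itself. Log2 departures from the sum were 1.76 for HMOX1, 1.49 for LINC01139, 1.40 for ITGA10, 1.37 for MT-RNR1, 1.33 for LINC00622 and SMPDL3A, 0.87 for TYR, 0.68 for MITF and 0.39 for HEY1. They were -2.16 for FLNC, -2.14 for G0S2, -2.02 for NRARP, -1.89 for KRT7, -1.82 for IGFN1 and GRAMD2B, -1.67 for SLC27A2, -0.76 for CDKN1A, -0.74 for PLK1, -0.63 for BUB1, -0.55 for ASNS and HES1, -0.51 for MYC and -0.48 for MCM4.

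Other splits of the same libraries were tested for each comparison. For the number of genes called, only 1 split, the real one, gave as many in each of the 5 comparisons of 2 groups. That argues against chance but does not exclude it. The lowest share possible is 1 of 35, and these counts were not adjusted for one another. These splits address the spread between these libraries only. The real and highest other counts were 5829 and 0 for BI6727 against DMSO, 4886 and 891 for MK-0752 against DMSO, 8406 and 0 for the combination against DMSO, 4738 and 1 against BI6727, and 4655 and 1895 against MK-0752, each over 35 splits. For the number of gene lists, the real split called the most for the combination against BI6727 (22 lists, highest other 18) and against MK-0752 (17, highest other 11). The same limits hold for these 2 list counts, so chance was not excluded for them either. Nor was it excluded for BI6727 against DMSO (8 lists, highest other 10, with 12 of 35 splits calling as many), MK-0752 against DMSO (15, highest other 17, 2 of 35) or the combination against DMSO (19, highest other 21, 2 of 35). The other splits that called as many kept most libraries of each group together, and so part of the treatment difference. Splits with 2 libraries of each group on either side called at most 2, 3 and 1 lists in these comparisons. There the treatment difference adds to the spread, so these counts do not decide on chance either. For the departure, splits of all 16 libraries also move the agents' own effects and say nothing of chance (2508 genes, highest other 2344, 1 of 100; 12 lists, highest other 17, 16 of 100). Shuffled residuals of the additive fit, chosen after these values were seen, argued against chance: with limma on log2 CPM 2480 genes were called, highest other 1, and 12 lists, highest other 10, each with 1 of 100 draws, the real one included, as large.

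MK-0752 replicate 1 stood apart from the other MK-0752 libraries. A label exchanged with a group given no MK-0752 was argued against by HES1, at 10.3 CPM in this library, 9.88 to 10.9 in the other 3 and 92.7 to 143 in the libraries given no MK-0752. An exchange with a combination library was argued against by 524 genes that differed 2-fold between the combination and the other 3 MK-0752 libraries. On a scale from 0 at the MK-0752 mean to 1 at the combination mean, this library had a median of -0.02 over them (quartiles -0.30 and 0.26), and HMOX1 was 29.8 CPM against 113 to 153 in the combination. A sample from outside the series was not tested for. Its library size was argued against as the whole cause, since among genes of 100 CPM or more its deviation had an SD 15.8 times that of counting noise. Its deviation followed transcript GC content across genes (r = 0.77), and the GC correction removed 60.2% of the variance, so a GC bias is a candidate explanation for that part. The correction subtracts a GC trend fitted to each library, so this share largely restates the correlation and is not separate evidence. Such a trend was not particular to this library, with r = 0.77 in combination replicate 1 and 0.72 in DMSO replicate 4. The SD of its log2 deviation from the other 3 was 0.50, against 0.28 in combination replicate 1 and 0.13 in DMSO replicate 4, and after the correction it was 0.31, against 0.07 to 0.15 in the other 15 libraries. Combination replicate 1 also stood apart, with a chi-square per degree of freedom of 14.7 to 29.2 to the other combination libraries, against 2.11 to 5.38 among those, and its deviation correlated at 0.47 with that of MK-0752 replicate 1. What lies behind the bias stays open, and no biological explanation was tested.

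Long noncoding RNAs, 1927 of them tested, had median log2 fold changes of -0.30 with BI6727, -0.26 with MK-0752 and -0.41 with the combination, against 0.01, 0.04 and 0.03 for protein-coding genes. GC content was argued against, since the difference for the combination was -0.45 after the GC correction. Genomic DNA in the DMSO libraries would also raise pseudogenes, whose medians were -0.06 with each agent and -0.20 with the combination. It was argued against by 1512 protein-coding genes at 0 counts in the treated libraries, which held 0.00082 CPM per kb in DMSO, 0.51% of the smallest median fall of long noncoding RNAs (0.161 CPM per kb, with MK-0752, quartiles -0.046 and 0.575). Against protein-coding genes matched on mean CPM the difference for the combination was -0.13. That is much smaller than against all protein-coding genes (-0.41 against 0.03), so much of the pattern goes with low expression. It lies between the bounds set for either outcome, so low expression cannot be told apart from the pattern as a whole. An effect of the agents on these RNAs stays among the open explanations. So does a deviation common to the DMSO libraries, which the comparisons with DMSO share, and this was not tested. These RNAs took 1.19 to 1.21% of counts in DMSO. They took 0.941 to 0.953% with BI6727, 0.898 to 1% with MK-0752 and 0.902 to 0.952% with the combination. Against BI6727 and MK-0752 the combination had medians of -0.10 and -0.12. The departure from additivity had a median of 0.18 (264 above, 71 below), which a higher DMSO level would also favour.

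Mitochondrially encoded transcripts were higher in the combination than in DMSO, with a median log2 fold change of 0.87. GC content was argued against by a median of 0.77 after the GC correction, and a single combination library by a lowest median of 0.83 over the left-out libraries. For more mitochondria per cell, nuclear oxidative phosphorylation genes were predicted to rise as well, and their median was -0.01. So these nuclear genes did not rise together with the mitochondrially encoded ones. Their levels are relative to other transcripts and do not count mitochondria, so this cannot decide whether cells held more mitochondria. Without MK-0752 replicate 1, a setting chosen after the data were seen, MK-0752 alone had 12 of 13 higher than DMSO (median 0.45, adjusted p = 3.6e-05; 1 of 13 and 0.82 with it), and the combination stood above MK-0752 by a median of 0.46 instead of 0.74. A change in mitochondrial transcripts with MK-0752, given alone or with BI6727, is a hypothesis found and tested on the same data, and for the combination against DMSO the list did not pass with an estimated correlation (adjusted p = 0.46).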

How the results depend on the processing

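The GC correction, the removal of MK-0752 replicate 1 from comparisons without that group and the leave-outs for correlations were chosen only after the data were seen. The cause of a difference between settings was not tested unless the setting itself shows it. Of 1729 values of named genes under other settings, 1675 kept their direction and side of the threshold, 32 lost and 17 gained a call and 5 reversed. With a library left out, 1681 of 1723 did, 29 lost and 7 gained a call and 6 reversed. Of 547 calls of gene lists 459 held, and 834 of 889 with a library left out. The median change of all tested genes was -0.103 for the combination against MK-0752 on log2(TPM + 1), against -0.026. The 1 added to TPM by itself shrinks log2 changes of genes at low TPM, and that setting used no TMM factors. How much of each difference comes from either was not tested.

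After the GC correction, genes called lower numbered 4721 with BI6727, 4061 with MK-0752 and 3658 in the combination against BI6727, and 4486 genes departed from additivity, 2330 above and 2156 below. With limma on log2(TPM + 1), genes called higher numbered 2384 in the combination against DMSO, 1140 against BI6727, 765 against MK-0752 and 719 for the departure. The combination lowered 2819 genes among those of a mean CPM of 5 or more, where fewer genes were tested. With only the groups compared, 8806 genes were called with BI6727, 4602 higher, and 3493 with MK-0752, 1635 higher and 1858 lower. In the combination against MK-0752 the same setting called 2063 genes, 918 higher and 1145 lower.

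Some uncalled genes changed sign. In the combination against BI6727 NOTCH2 had -0.03 and NOTCH3 0.05 on log2(TPM + 1). In the combination against MK-0752 NOTCH2 had -0.01 on that scale, and NOTCH1 0.02 with limma-voom and 0.26 after the GC correction. With libraries left out in turn, NOTCH1 ranged from -0.02 (without MK-0752 replicate 1) to 0.58 with MK-0752, from -0.42 to 0.03 (without combination replicate 4) in the combination against BI6727, and from -0.35 to 0.38 (without MK-0752 replicate 1) against MK-0752.

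With libraries left out, genes called higher ranged from 1838 to 3664 with MK-0752 and from 1916 to 3900 in the combination against BI6727. The departure ranged from 1907 to 4158 genes, 950 to 2134 above and 897 to 2024 below. Each highest value was without MK-0752 replicate 1.

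Over all comparisons 93 lists were called, 37 with an estimated correlation and 162 with fry, which does not compare a list with other genes. The correlation of the agents' responses was 0.66 among genes of a mean CPM of 5 or more, 0.64 to 0.70 with a library left out, and 0.57, 0.59, 0.55, 0.59, 0.51 and 0.50 for the splits of the DMSO libraries. The effect of an agent with and without the other correlated at 0.60 for MK-0752 and 0.64 for BI6727 among genes called for that agent alone.

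Replicate numbers did not pair the libraries: of 24 pairs of same-numbered libraries 5 had deviations from their group means that correlated over 0.1, from -0.34 to 0.47, and 3 of 16 libraries lay closest to their own number. With the number as a block, 5683, 4652, 8336, 4557, 4434 and 2271 genes were called in the 6 comparisons in the order of the report, and 90 of the 93 list calls held. Of simulated 1.5-fold departures 45% were recovered among 15981 genes, against 69 to 74% of 1.5-fold changes between 2 groups.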

Other observations

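With both agents, type I interferon genes were lower than with MK-0752 alone in 8 of 23 members with 2 higher (median -0.32, adjusted p = 0.0021; median -0.19, adjusted p = 0.0048 without MK-0752 replicate 1; adjusted p = 0.1 with an estimated correlation). NF-kB and secretory cytokine genes were lower than with MK-0752 alone in 6 of 19 members with 2 higher (median -0.35, adjusted p = 0.015; median -0.18, adjusted p = 0.042 after a GC correction; adjusted p = 0.074 with an estimated correlation). Counts adjusted over the list alone were 9 and 8 lower. Heat shock genes lay below the sum of the changes of the agents in 7 of 14 members (adjusted p = 0.085 with an estimated correlation), and homologous recombination genes in 6 of 18 (adjusted p = 0.14 with an estimated correlation), and 8 and 9 when adjusted over the list alone. After a GC correction 11 homologous recombination genes lay below.

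Of the 2508 genes that departed from additivity, 1114 were called in the same direction with each agent and fell short of the sum, and 93 were called in the same direction with each and went beyond it. Shared libraries favour the first of these. So would a deviation common to all DMSO libraries or to all libraries of an agent, which separate libraries do not remove. With the departure called in 2 libraries per group and the agents in the other 2, the counts were 111 and 6, 119 and 9, and 92 and 8 for the departure from replicates 3 and 4, 2 and 4, and 2 and 3, and with replicate 1 among the 2 edgeR called 0 departures (1763 to 2076 genes at an unadjusted p under 0.05). Another 477 were called with neither agent, and 63 were called in opposite directions with the agents.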
